A study of Homo sapiens with 6 samples.

How the data were processed

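The data are RNA sequencing libraries from CAL-27 cells in 2 groups, NC (n = 3) and shYTHDC2 (n = 3), with groups and replicate numbers taken from the sample titles. Per the labels' protocols, poly(A) RNA was selected, fragmented and made into dUTP-marked, strand-specific libraries, which were sequenced as paired ends on an Illumina NovaSeq. The submitters' processing notes name fastp, HISAT2, StringTie and edgeR, and the build GRCh38, without versions or roles. The strand setting of the counting and the gene annotation are not given in the sources used here, so a gene and its antisense or overlapping partner cannot be told apart with certainty.

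The table analysed holds, per the file headers, FPKM values of each library as deposited by the authors, that is fragments scaled to transcript length and to the library total. It also holds the authors' fold, a ratio, which was equal to the ratio of the mean FPKM of the groups with 0.0001 in place of a mean of 0. The authors' log2 fold change is the log2 of that ratio, per the file headers and checked on the values. The authors' deposited p-value and q-value columns stand beside it, with the test not named. The table listed 402 genes, 402 of them marked up and significant. No count or depth is given, so no counting interval or detection floor was computed, and a value of 0 is described as listed at 0. FPKM divides by each library's total, so a change in a few abundant genes shifts all others, and values of low genes rest on few fragments.

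The authors' p and q values were used to ask how many genes they had tested. If q is the Benjamini-Hochberg adjustment of p, then 30944 tested genes give whole ranks, within 0.01, for 370 of the 400 genes with p above 0 (92.5%), where the next best number, 46416, gives 45.25%. The last listed gene would then have rank 4445, and the 402 genes would be 9.04% of the genes, of either direction and any fold, with a p that low. This is an inference from the columns and not a statement of the authors.

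The test was planned for a table of all genes. It was run as planned on the listed genes, and its results describe genes already selected by the authors for a higher level. Values were transformed as log2(FPKM + 1), genes with a mean of at least 1 FPKM in 1 or both groups were kept (187 genes), and limma 3.58.1 in R 4.3.3 was fitted with the group as the only term, with trend and robust variance, and Benjamini-Hochberg adjustment at 0.05. No scaling was applied beyond that of FPKM. The step was tested on simulated data for 184 genes at 3 against 3, where it called 86.8% of genes changed 2-fold, 69.7% at 1.5-fold, 35.7% at 1.2-fold and 2.35% of unchanged genes. The simulated spread was that of the listed genes, every simulated change was a rise, and only 85 of the 184 genes were unchanged. These rates therefore do not carry over to a table of unselected genes. An exact two-sided permutation test of 3 against 3 cannot go below 0.1, so none is reported for single genes.

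Gene lists, 38 in all, were fixed before the data were examined, as were the groups, the test, the alternatives and the rule for named genes. Lists with at least 5 tested genes were tested by camera with a preset correlation of 0.01, by camera with an estimated correlation, and by fry. In the table with the filter this was 1 list. No enrichment against the genome was computed, because the genes that could have passed the authors' criteria were not analysed here. The rule named YTHDC2, the 8 protein-coding genes with the largest rise and the 8 with the largest fall among those past the test with separated groups and with a gene symbol (clone names, antisense and pseudogene names left out), the 3 members with the smallest adjusted p of each list that passed camera or had 5 members past the test, and up to 2 members of any other list. It gave no fall, and 21 of its genes are reported. The others, and the lists in which such a gene alone was listed, are not reported here.

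The libraries were compared before averaging. Within groups the correlation of log2 values across the 187 kept genes was 0.984 to 0.989. The median coefficient of variation of these genes was 13.0% in NC and 9.16% in shYTHDC2. Among all listed genes, 0 had identical values above 0 in any pair of libraries of a group. The authors had selected the listed genes as significant, which favours a low spread within groups, so these figures may not hold for other genes. All 6 libraries were kept.

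Alternatives were a TMM-like scaling (the trimmed mean of log ratios, without weights), quantile normalization, pseudocounts of 0.1 and 0.01, no filter, a filter of 1 FPKM in 3 libraries or a mean of 5 FPKM, limma without trend and robust variance, the replicate number as a block, each library left out in turn, a 2-fold minimum, an adjusted p of 0.01, protein-coding genes alone, and the authors' own calls. Scaling within each group was added after seeing the data. Gene types and positions come from GENCODE release 29, in which 377 of the 402 identifiers were found. The 3′ UTR sequences were taken from the same release. Tables were joined and drawn with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.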

Results

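RNA sequencing of CAL-27, an established cell line of oral squamous cell carcinoma, was used to ask what a knockdown of YTHDC2 does to gene expression. YTHDC2 is an RNA helicase that binds N6-methyladenosine (m6A), a methyl mark on RNA. The 6 libraries fell into 2 groups, NC (n = 3) and shYTHDC2 (n = 3), numbered as biological replicates. The labels give no account of separate cultures or days, so p-values measure the spread between these libraries. Expression was given as FPKM, with the sequencing depth of each library unknown.

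The table analysed here held 402 genes, each marked by the authors as higher in shYTHDC2 and as significant. In the authors' deposited table the smallest fold was 2.00 and the largest q was 0.0494. Genes lower in shYTHDC2, and genes that differed by less than 2-fold, were not analysed here. The level of YTHDC2 itself was not analysed here either, so the group labels were not checked against the targeted gene. Every test that follows was run on genes already selected for being higher, so the direction was fixed beforehand and the p-values are smaller than they would be for unselected genes.

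Genes for secreted signals, a cytoskeletal protein and a hair keratin-associated protein were among the 8 largest rises of protein-coding genes with a symbol. KRTAP2-3, a keratin-associated protein, went from 0.416 ± 0.26 FPKM in NC to 5.81 ± 0.20 in shYTHDC2 (SD, n = 3 in each group, as for all values that follow). EDN1, which encodes the vasoconstrictor peptide endothelin-1, rose from 3.03 ± 0.88 to 16.4 ± 1.8 FPKM, a 5.40-fold difference. PTX3, a soluble pattern recognition protein, rose from 7.04 ± 0.33 to 30.8 ± 2.1 FPKM, and the cytokine IL6 rose from 7.13 ± 0.62 to 29.8 ± 2.8 FPKM. TPM4, an actin-binding tropomyosin, rose from 15.5 ± 1.4 to 66.6 ± 1.5 FPKM, and SERPINB2, an inhibitor of plasminogen activators, from 13.5 ± 1.8 to 53.1 ± 2.2 FPKM.

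On the log2(FPKM + 1) scale, which understates the change of low genes, KRTAP2-3 changed by 2.28 (SE 0.12), EDN1 by 2.12 (SE 0.15), TPM4 by 2.04 (SE 0.06) and PTX3 by 1.98 (SE 0.07). IL6 changed by 1.92, SERPINB2 by 1.90 and the collagen gene COL8A1 by 1.66, each with an SE of 0.08. The limma adjusted p of these 7 genes lay between 9.89e-09 for TPM4 and 1.59e-06 for EDN1. TEN1, a subunit of the telomere-associated CST complex, changed by 1.83 with the widest error of the 8 (SE 0.40, limma adjusted p = 5.03e-03). All 3 shYTHDC2 libraries lay above all 3 NC libraries for each of the 8 genes, as the rule that named them required. TEN1 lost its call under the TMM-like and quantile scalings across groups (limma adjusted p = 0.147 and 0.145). KRTAP2-3 has a near-identical neighbour, KRTAP2-4, listed at 0 in all NC libraries and at 0.889 ± 0.15 FPKM in shYTHDC2, and TPM4 has the listed pseudogenes TPM4P2 and TPM4P3, so the split of reads among these copies is uncertain. TEN1 overlaps the annotated readthrough gene TEN1-CDK3 and is uncertain for the same reason.

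In GRCh38, with positions from GENCODE release 29, KRTAP2-3 (ENSG00000212724) lies on chromosome 17 from 41059240 to 41060114, and TEN1 (ENSG00000257949) on the same chromosome from 75979220 to 76000586. EDN1 (ENSG00000078401) spans 12290363 to 12297194 on chromosome 6, TPM4 (ENSG00000167460) 16067021 to 16103005 on chromosome 19, and IL6 (ENSG00000136244) 22725884 to 22732002 on chromosome 7. PTX3 (ENSG00000163661) spans 157436789 to 157443628 and COL8A1 (ENSG00000144810) 99638475 to 99799226, both on chromosome 3. SERPINB2 (ENSG00000197632) spans 63871692 to 63903890 on chromosome 18.

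**Figure D1:**
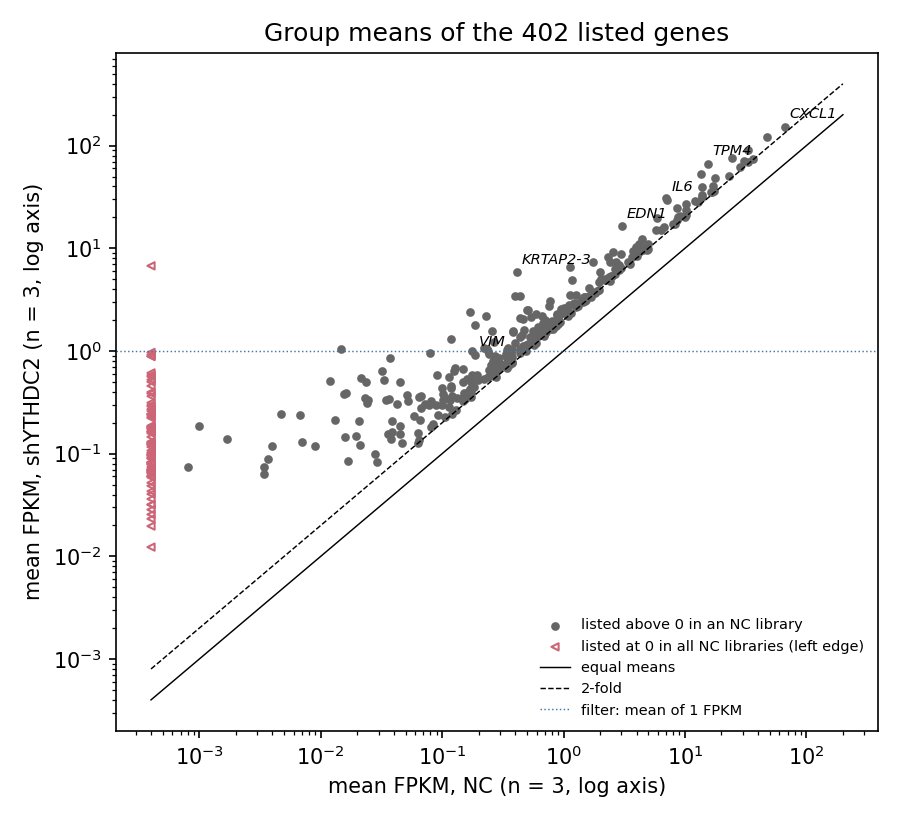
Mean FPKM of each of the 402 listed genes in NC (horizontal log axis, n = 3) and shYTHDC2 (vertical log axis, n = 3), with 1 point per gene and lines for equal means, a 2-fold difference and the filter at a mean of 1 FPKM. All points lie above the 2-fold line because the table was selected that way, and the 84 genes listed at 0 in all NC libraries stand at the left edge, where their horizontal place has no scale.

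Among 38 gene lists fixed before the data were examined, inflammatory cytokines and NF-kB targets had 5 of 28 genes in the table, and all 5 rose (5 adjusted over the list alone), although CXCL1 and CSF3 turned below 0 under a TMM-like scaling across groups and CSF3 under a quantile scaling, which place a gene that rose less than the typical listed gene near or below 0. CXCL1, a neutrophil-attracting chemokine, had the highest shYTHDC2 level of the table, 153 ± 5.0 FPKM against 67.2 ± 1.3 in NC (log2 change 1.17, SE 0.04). LCN2, which binds iron-carrying siderophores, rose from 33.1 ± 2.1 to 89.7 ± 1.3 FPKM (log2 change 1.41, SE 0.05), a call lost under the TMM-like scaling (limma adjusted p = 0.577). The chemokine CCL20, at 5.84 ± 0.76 and 19.6 ± 3.0 FPKM, and CSF3, the granulocyte colony-stimulating factor, at 0.631 ± 0.26 and 1.58 ± 0.73 FPKM, completed the list together with IL6; CCL20 and CSF3 are named after their values were seen.

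The median log2 change of these 5 genes was 1.41, against 0.88 over the 187 tested genes of the table. Against those other genes, themselves all listed as higher, the list gave an adjusted p of 0.0492 in camera with its preset correlation. With an estimated correlation the adjusted p was 0.181, which ends the call. Only 1 list had enough genes to be tested here, so in camera and in fry its adjusted p equals its unadjusted p. These values hold no correction over the other fixed lists. The fry test, which asks whether the genes move one way, gave 7.08e-06. The selection of higher genes fixed that direction beforehand, so no conclusion is drawn from it. The camera call was also lost without NC replicate 3 (adjusted p = 0.163) and without shYTHDC2 replicate 2 (0.0556). It was lost too with a pseudocount of 0.01 (0.0508), with a filter of 1 FPKM in 3 libraries (0.0744), without limma's trend (0.205) and under the TMM-like scaling (0.229). Without shYTHDC2 replicate 3, 2 lists were tested and neither passed, and the smaller of their camera adjusted p-values was 0.0836. Across the camera settings with 1 list tested the adjusted p ranged from 0.00277 to 0.229.

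Genes of the mesenchymal transition list made up the largest number from any list, 7 of 25. COL5A1, a fibrillar collagen, rose from 13.9 ± 0.68 to 31.2 ± 0.96 FPKM (2.24-fold). Fibronectin, FN1, stood at 10.2 ± 0.76 and 21.1 ± 1.5 FPKM, and lysyl oxidase, LOX, at 4.02 ± 0.32 and 8.49 ± 0.47 FPKM. All 4 tested members of the list passed limma (4 adjusted over the list alone), and these 3 turned below 0 under the TMM-like and quantile scalings across groups. The intermediate filament gene VIM (0.186 ± 0.091 and 0.918 ± 0.31 FPKM), the transcription factor ZEB1 (0.377 ± 0.088 and 0.787 ± 0.059 FPKM) and ACTA2 (0.162 ± 0.044 and 0.397 ± 0.057 FPKM) were under the filter and not tested. VIM lies against the listed antisense gene VIM-AS1, so its reads are uncertain. With no filter, the 7 genes gave a camera adjusted p of 0.0581, and 0.122 with an estimated correlation. FN1, LOX, VIM, ZEB1 and ACTA2 are named after their values were seen.

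The interferon response list had 3 of 38 genes in the table, all 3 past limma (3 adjusted over the list alone) and all 3 below 0 under both scalings across groups. IFIT2, an interferon-induced antiviral protein, rose from 17.3 ± 1.2 to 36.1 ± 1.8 FPKM and IFI6 from 36.6 ± 3.3 to 73.8 ± 4.1 FPKM, which are 2.09-fold and 2.02-fold differences. The squamous differentiation list had 2 of 35 genes, both cornified envelope precursors and both past the test (2 adjusted over the list alone). SPRR2D rose from 0.187 ± 0.12 to 1.79 ± 0.70 FPKM and SPRR2A from 0.0147 ± 0.025 to 1.04 ± 0.62 FPKM. They are close paralogs and their separate values are uncertain, and both lost their call under the quantile scaling (limma adjusted p = 0.0815 each).

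Single genes stood for 5 further lists, each past limma (1 adjusted over the list alone). HBEGF, a ligand of the EGF receptor on the EGFR and MAPK signalling list, rose from 16.9 ± 1.1 to 40.8 ± 1.5 FPKM, and CCN2, a matricellular protein of the YAP target list, from 16.4 ± 1.1 to 35.2 ± 3.3 FPKM. Genes that rose at lower levels were NGFR of the basal keratinocyte list (0.733 ± 0.33 and 1.72 ± 0.36 FPKM), AKR1C1 of the oxidative stress and ferroptosis list (0.806 ± 0.13 and 1.96 ± 0.11 FPKM) and the ligand WNT5A of the Wnt target list (0.223 ± 0.029 and 1.07 ± 0.17 FPKM). WNT5A lies against its listed antisense gene and is uncertain. HBEGF, CCN2, NGFR and AKR1C1 turned below 0 under both scalings across groups, and WNT5A lost its call under both (limma adjusted p = 0.0830 and 0.233).

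Of the marker lists for other cell types, the endothelial list had 2 of 10 genes in the table. The cadherin CDH5 rose from 1.52 ± 0.12 to 3.12 ± 0.41 FPKM (1 of 1 tested, 1 adjusted over the list alone), again below 0 under both scalings, and ESAM, named after its values were seen, stood at 0.286 ± 0.10 and 0.736 ± 0.099 FPKM, under the filter. The lists of fibroblast (12 symbols), leukocyte (16), neuroendocrine and embryonic kidney (11), and simple glandular epithelium markers (13) had 0 genes in the table. Genes of these cell types outside the short lists were not counted. The list of YTHDC2 partners and meiosis had 1 of 27 genes, DMC1, a meiotic recombinase at 0.0676 ± 0.035 and 0.367 ± 0.11 FPKM, which was not tested.

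Lists with 0 genes in the table numbered 25. Besides those 4 marker lists they were m6A machinery, RNA decay, epithelial junction, matrix proteases, S phase and replication, G2/M and mitosis, p53 targets, antigen presentation, unfolded protein and integrated stress response, glycolysis and hypoxia, cholesterol synthesis, fatty acid synthesis, mitochondrial encoded genes, nuclear oxidative phosphorylation, ribosomal proteins, Notch pathway, immediate early and heat shock genes, replication dependent histones, autophagy and lysosome, DNA repair, and head and neck drivers. A gene's absence shows only that it was not listed as at least 2-fold higher. A count of 0 covers only the symbols on a list, and related genes outside the lists were not counted. Some of these were in the table, such as the metalloproteases MMP24 (3.30-fold) and ADAM12 (2.69-fold). Others were the DNA repair gene RAD51B (2.21-fold) and the p53 target PERP (2.10-fold). These genes are named after their values were seen.

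**Figure D2:**
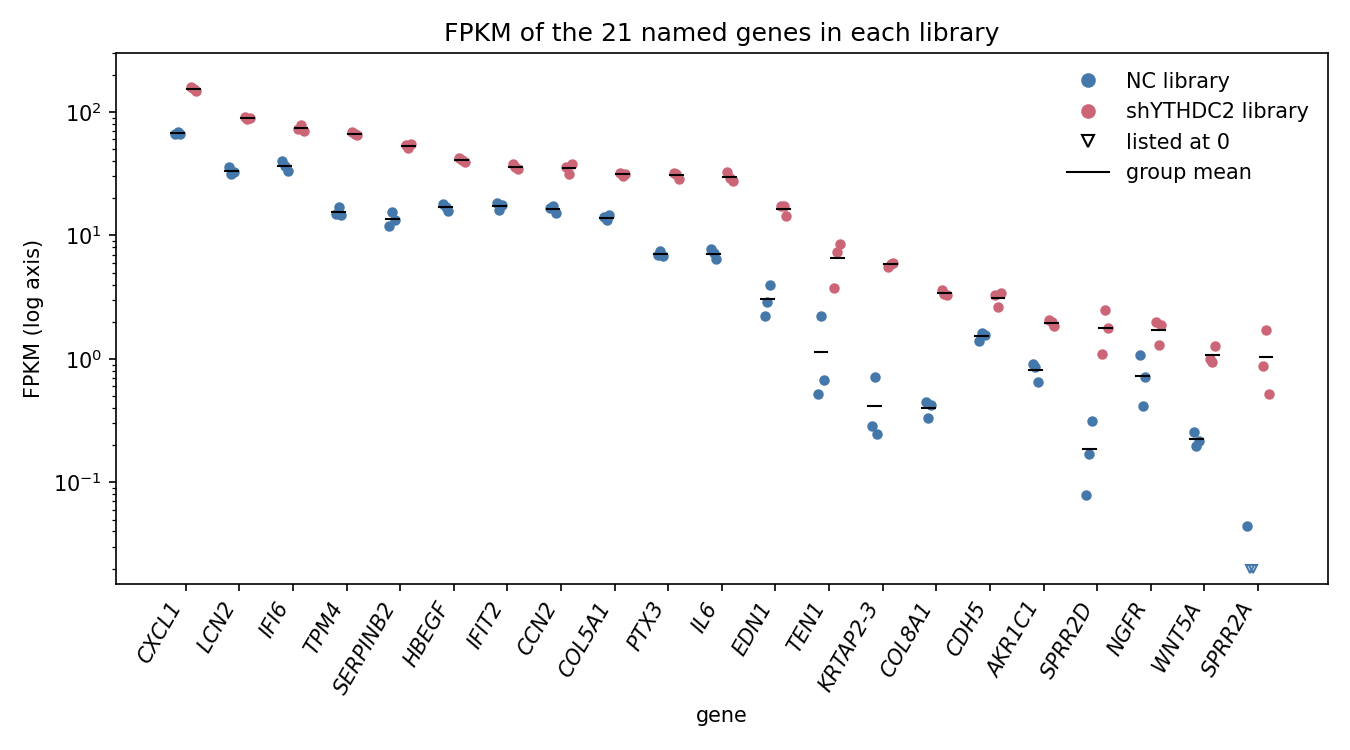
FPKM (vertical log axis) of the 21 genes drawn from the fixed rule (horizontal axis) in each NC (blue) and shYTHDC2 (red) library, with a black bar at each group mean (n = 3) and open triangles for libraries listed at 0. The shYTHDC2 libraries lie above the NC libraries for every gene drawn, from CXCL1 at a mean of 153 FPKM to SPRR2A at 1.04 FPKM, as the values were given by the authors; 9 of these genes turned below 0 under the TMM-like scaling across groups and 8 under the quantile scaling.

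Of the 402 genes, 283 were protein-coding, 85 were long noncoding RNAs, 20 were pseudogenes and 14 were of other kinds. A mean of at least 1 FPKM in either group was reached by 187 genes, among them 165 protein-coding genes and 15 long noncoding RNAs, and 43 genes had a shYTHDC2 mean of at least 10 FPKM. For the 186 of these 187 genes with signal in NC the median fold was 2.40, and 143 were under 3-fold. All 3 shYTHDC2 libraries lay above all 3 NC libraries for 364 of the 402 genes. Chance gives 5% in that direction without selection, but these genes were selected for being higher, so that share is no reference here.

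In limma, 185 of the 187 genes were higher in shYTHDC2 and 0 were lower, a count of 0 that the selection of the table sets. The genes that did not pass were the pseudogene MEMO1P1 (log2 change 0.89, SE 0.47, limma adjusted p = 0.114) and the long noncoding RNA ENSG00000293183 (0.76, SE 0.40, limma adjusted p = 0.110), both named after their values were seen. Scaling the libraries to one another on the listed genes moved the median log2 change from 0.88 to -0.07 (TMM-like) or -0.09 (quantile) and left 22 genes higher and 22 lower, or 18 higher and 8 lower, since such scaling takes most genes of the table to be equal between groups. It set 126 (TMM-like) or 132 (quantile) of the 187 genes below 0, so a turned sign or a lost call shows how a gene's rise compared with that of the other listed genes, and not whether it rose.

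A further 84 genes were listed at 0 in all 3 NC libraries. Of these, 50 had signal in 3 shYTHDC2 libraries, 24 in 2 and 10 in 1. With no filter, limma called 36 of the 84 genes. ENSG00000251537, a protein-coding gene on chromosome 17 from 15571491 to 15651653 that overlaps other genes on its strand, was the 1 gene of the 84 with a mean above 1 FPKM, at 6.75 ± 1.0 in shYTHDC2 (limma log2 change 2.95, SE 0.10, adjusted p = 1.31e-08). That was the largest change among the 187 tested genes, but the rule for named genes takes genes with a symbol and this one has none in the table, so it is named after its values were seen. No fold is given against a group listed at 0.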

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

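The scaling within each group was chosen only after the result was seen; the other alternatives were planned. The count of 185 genes higher in shYTHDC2 was 172 to 187 under both other pseudocounts, the filter of 1 FPKM in 3 libraries, limma without trend and robust variance, an adjusted p of 0.01 (184), scaling within each group (185), and each library left out in turn (183 to 187), and 164 among protein-coding genes alone. It was 342 with no filter and 74 with a mean of 5 FPKM, because more or fewer genes were tested, 67 with a 2-fold minimum, and 402 as the authors called them. It was 44 (22 higher, 22 lower) under the TMM-like scaling and 26 (18 higher, 8 lower) under quantile normalization, which take the typical gene of the table as equal between groups.

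With the TMM-like scaling the log2 change turned to -0.0623 for NGFR, -0.22 for COL5A1, -0.32 for IFIT2, -0.38 for IFI6, -0.21 for CXCL1, -0.0602 for AKR1C1, -0.28 for CCN2, -0.12 for HBEGF and -0.25 for CDH5. With quantile normalization it turned to -0.0843 for NGFR, -0.15 for COL5A1, -0.25 for IFIT2, -0.25 for IFI6, -0.0714 for AKR1C1, -0.25 for CCN2, -0.0913 for HBEGF and -0.20 for CDH5. Of the 21 named genes, 3 others lost their call without turning under the first scaling (TEN1, LCN2 and WNT5A) and 5 under the second (TEN1, SPRR2D, SPRR2A, WNT5A and CXCL1, which stood at 0). Those with a value kept direction and call under the other alternatives.

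The 1 list past camera fell to 0 under the TMM-like scaling, a pseudocount of 0.01, the filter of 1 FPKM in 3 libraries, limma without trend, and an estimated correlation, and was 0 to 1 with each library left out; the cause was not tested. With a mean of 5 FPKM no list had 5 genes. The level of YTHDC2 has no value under any setting.

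With the replicate number as a replicate block, 183 genes passed and the list kept its call. The labels state no pairing, so the planned fit did not take the numbers as pairs. Same-numbered libraries had correlations of deviations of 0.06, 0.15 and 0.07, and each library correlated best with its own number, so a pairing stays open. Depth is unknown, which limits the genes under 1 FPKM most.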

Other observations

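The tests of the genes seen in 1 library, of the placement of zinc finger genes, and of the control words and the reversed site in 3′ UTRs were chosen only after the result was seen; the others were planned before their result.

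Several abundant genes outside the lists, chosen after their values were seen, also differed between the groups. GANAB, a glucosidase subunit of the endoplasmic reticulum, stood at 47.0 ± 1.1 FPKM in NC and 121 ± 4.4 in shYTHDC2 (SD, n = 3 in each group), and B4GALT1, a galactosyltransferase, at 30.6 ± 0.38 and 71.5 ± 2.7 FPKM. The galectin LGALS1 stood at 24.6 ± 1.5 and 76.2 ± 5.6 FPKM, and the receptor subunit IL7R at 13.9 ± 0.15 and 39.6 ± 1.6 FPKM. These were 2.57-fold, 2.33-fold, 3.09-fold and 2.84-fold differences, with limma adjusted p between 9.89e-09 and 2.77e-08. Under the TMM-like scaling LGALS1 (0.23) and IL7R (0.10) kept their sign, and GANAB (-0.04) and B4GALT1 (-0.17) did not.

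Low genes with large ratios included IL24, a cytokine of the IL10 family, at 0.439 ± 0.19 and 2.08 ± 0.30 FPKM, and IGFBP1, an insulin-like growth factor binding protein, listed at 0 in NC and at 0.611 ± 0.11 in shYTHDC2. The tropomyosin gene TPM1, a relative of TPM4, stood at 0.584 ± 0.14 and 1.46 ± 0.049 FPKM. VIM and FN1, which fibroblasts express strongly, differed by 0.732 and 10.9 FPKM between the group means. These genes too were chosen after their values were seen.

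Of the 10 ways to split the 6 libraries into groups of 3, the real one called 185 of the 187 genes and the highest of the others called 0. It is 1 of 10, and 10 splits are too few for a share under 0.05. The genes had also been selected by the authors on the real split. A higher count for that split was therefore set beforehand, and no conclusion about chance is drawn from it.

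The authors called 10 genes that were listed at 0 in 5 of the 6 libraries. FMC1-LUC7L2, for example, has 1.58 FPKM in shYTHDC2 replicate 1 and 0 in the others, with a q of 5.62e-07 in the authors' deposited table. With no filter limma called 0 of the 10, 0 also at an unadjusted p under 0.05. That outcome was largely set beforehand, since the genes were chosen for signal in 1 library. Of the 9 with an annotation, 8 (88.9%) overlap another gene on their strand or are pseudogenes, against 61 of 182 (33.5%) genes with a mean of at least 1 FPKM (Fisher's exact test, two-sided, p = 0.0014). The comparison genes had higher levels and were mostly protein-coding (165 of 187), and other low genes were not compared, so the excess may hold for low genes in general. Assignment of shared reads to a different copy in each library is a candidate explanation that this test cannot single out, and no biological explanation was tested.

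Zinc finger genes of 1 stretch of chromosome 19 (51964343 to 53458261) recurred in the table, 6 of the 33 annotated there: ZNF350, ZNF616, ZNF468, ZNF845, ZNF765 and ZNF761. The densest 30 consecutive zinc finger genes of the genome held 5 listed genes, where random placement of the 13 listed ones held 2.67 on average (permutation p = 0.018, one-sided). The stretch was noticed first and tested on the same data, and the draws used all 509 annotated zinc finger genes, expressed or not. This test therefore cannot decide on chance placement. Reads shared between paralogs are argued against for most of these genes by a median of 1.04% of 100-base stretches found in another gene, but ZNF468 shares 99.1%. A single change of DNA dose cannot be told apart from separate changes, since none of the 5 genes with signal in every library departed from their mean past the threshold (limma, smallest adjusted p = 0.106) with 3 libraries a group; ZNF350, listed at 0 in NC, was not tested. ZNF616, at 0.463 ± 0.037 and 2.03 ± 0.19 FPKM, and ZNF845, at 0.761 ± 0.15 and 2.76 ± 0.11 FPKM, had the highest levels in shYTHDC2. An effect of the knockdown on the cluster stays open.

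YTHDC2 binds m6A, and AU-rich elements mark unstable cytokine messages, so the 3′ UTRs of the 165 protein-coding genes with a mean of at least 1 FPKM were searched. The word TATTTAT occurred in 45.5% of them, against 33.7% of annotated genes matched on UTR length and GC content (95% of draws 27.3 to 40.0; permutation p = 0.0004, one-sided), and m6A consensus sites (DRACH) had 19.8 per kb against 18.8 (p = 0.009). Of the 20 other words of 5 T and 2 A, 0 had as large an excess as TATTTAT. However, 6 of the 21 words had a permutation p under 0.05, and these control words were chosen after the result was seen. Base composition therefore cannot be told apart for TATTTAT. For DRACH it cannot be told apart by the permutation test of the reversed site, which had 22.8 per kb against 22.6 (permutation p = 0.32, one-sided). A candidate explanation is that messages with AU-rich elements, or with more m6A sites, rose more often. The matched genes were not limited to those expressed in CAL-27, so a general feature of inducible genes in these cells stays open, and m6A itself was not measured here.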
